A study of Homo sapiens with 3 samples.

How the data were processed

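Gene expression was measured on 3 two-colour arrays of 30000 features. Each array carried RNA of the parental THP-1 line, a human monocytic leukaemia cell line, and RNA of 1 bortezomib-resistant line derived from it. Bortezomib is a proteasome inhibitor that binds the subunit encoded by PSMB5. Per the labels' protocols, resistance was built up over 6 months by stepwise exposure from 2.5 nM, with a parental IC50 of 3.3 nM, total RNA was extracted with RNA-Bee, and the parental RNA was labelled with Cy5 and the resistant RNA with Cy3. The final concentration was 30 nM for the line called BTZ30 and 100 nM for the line called BTZ100. The third line, called BTZ100 drug-free here, was a 100 nM line kept for 6 months without bortezomib. Every group held 1 array, with no replicate and no dye swap, so no p-value was computed and the number of arrays limits the precision.

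The deposited values were log ratios of the 2 channels as processed by the authors. The background correction, the normalization and the filter that emptied some spots are not given in the sources used here. The base of the logarithm is not stated. Base 10 was set aside because the most extreme deposited value, 5.24 in size, would then stand for a ratio of 174985, beyond what a scanner records. At base 2 a value of 1 is a 2-fold ratio, and at the natural base it is a 2.72-fold ratio. The direction is not stated either. The design text describes the resistant lines as hybridised against the parental line, which makes resistant over parental the likely direction, but the labels list the parental RNA as channel 1. Values are therefore given as above 0 or below 0. The median of each deposited column was 0.00, so centring each array on its median, the main setting, moved nothing. All per-sample columns of the value table were used.

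Features were named through the platform annotation supplied with the values. It gave 1 gene symbol for 19506 features and several for 59, and 10435 features were unnamed here. Symbols were updated through gene identifiers to the RefSeq names of the GRCh38.p14 assembly for 19377 features, and the older symbol was kept for 129. A gene's value was the median over its probes, and 14070 genes had a value on all 3 arrays. Of these, 13290 had 1 probe and 780 had 2 or more. The Y-linked genes and XIST, 29 of the 14070, entered the counts and are not reported by name.

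Genes at or beyond 1 unit of the deposited scale were counted on each side of 0 for each array and for 2 differences between arrays, BTZ100 minus BTZ30 and BTZ100 drug-free minus BTZ100. In a difference the parental channel cancels as far as both arrays carried the same parental RNA. Any gene-specific dye bias common to both arrays cancels too. For 23 gene lists the median member value was set against 10000 random lists with as many genes, matched on the number of probes per gene, since the file gives no intensity. A list median outside the central 95% of those random lists is a description of these arrays and not a test of the lines. Correlations were computed across genes, which are not independent replicates. They were set beside a simulation of 3 unchanged lines against 1 shared parental RNA, drawn as normal values of equal spread per RNA.

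The comparisons, the threshold, the gene lists, the rule for named genes and a set of other settings were fixed before the data were examined. The rule named the 12 genes on each side of 0 with the largest smallest value over the 3 arrays, the 5 most extreme genes on each side of each array, the 12 most extreme on each side of each difference, PSMB5, and list members at or beyond 1 with up to 4 examples where fewer passed. Those settings were values without centring, scaling of the arrays to 1 median absolute deviation, another probe summary, probes counted 1 by 1, thresholds of 1.5-fold and 3-fold at base 2, another rule for missing values, genes with 2 or more agreeing probes, and other summaries of lists and correlations. Settings added after the data were seen removed print-position medians, left out genes beside a like feature, assumed natural logarithms, kept the first 300 feature numbers of each run of 625, or matched random lists on print position.

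Values were present for 25054 features on the BTZ30 array, 25254 on the BTZ100 array and 23659 on the drug-free array. Technical spread within an array was read from the repeated GAPDH spots, whose SD was 0.107, 0.101 and 0.080 in that order over 304, 306 and 307 spots. These spots are of 1 gene and do not give the spread of other features. For 238 pairs of probes annotated to the same sequence record, the SD of the difference was 0.66, 0.66 and 0.49, which would include any misplaced names. The counting code was run on shuffled gene values held within 0.9 of 0, with 200 genes planted at 1.5 on either side, and all 200 were counted for each array, which checks the code and not the power of the arrays. Of 100 simulated lists of 16 genes shifted by 0.5, 100 fell outside the central 95% for each array, against 3, 0 and 5 of 100 unshifted lists for the BTZ30, BTZ100 and drug-free arrays. That shift is wider than the range itself, -0.268 to 0.164 for a list of 16 genes on the BTZ30 array. Lists starting inside the range thus had to leave it, and this too checks only the code. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.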

Results

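Transcript levels of 3 bortezomib-resistant derivatives of the monocytic leukaemia line THP-1 were each compared with the parental line on 1 two-colour array. The BTZ30 and BTZ100 lines had been selected to 30 nM and 100 nM of bortezomib, an inhibitor of the proteasome, and the drug-free line was a 100 nM line kept for 6 months without the drug. The share of empty spots was 16.5% on the BTZ30 array, 15.8% on the BTZ100 array and 21.1% on the drug-free array. Values are deposited log ratios of unstated base. A ratio of resistant over parental is likely from the wording of the design but is not settled by the labels, so signs are given as above or below 0. No comparison has a replicate, and no difference could be tested against biological spread.

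Sterol synthesis genes lay furthest below 0 among the gene lists in the BTZ30 line, selected to 30 nM. The 16 measured genes of cholesterol and isoprenoid synthesis had a median of -1.23, all 16 were below 0, and 12 were at or below -1. HMGCS1, which makes the precursor of mevalonate, stood at -2.58, DHCR7, which catalyses the last step of cholesterol synthesis, at -2.30, MVK, mevalonate kinase, at -2.01 and IDI1 at -1.81. Proteasome genes lay above 0. The 13 measured genes of the 20S core, the catalytic barrel, had a median of 0.36 and all 13 were above 0, with PSMB6 at 1.65. The 16 measured genes of the 19S regulatory particle, the cap that receives ubiquitinated proteins, had a median of 0.59 with 12 above 0, and PSMD2 stood at 1.26, PSMD14 at 1.18 and PSMC4 at 1.04. PSMB5, the subunit bortezomib binds, was at 0.22.

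Myeloid and antigen presentation genes lay below 0 in BTZ30. The 29 measured myeloid and monocyte genes had a median of -0.52 and 9 were at or below -1. Among the 9 were CSF1R, the receptor of macrophage colony-stimulating factor, at -2.40, the calcium-binding protein genes S100A9 at -2.14 and S100A8 at -1.95, and FCGR1A, a high-affinity Fc receptor, at -2.04. The 10 MHC class I presentation genes had a median of -0.44, with HLA-B at -1.06 and B2M at -1.002. Of the inducible proteasome subunits, PSMB9 stood at -1.70, PSMB8 at -1.08 and PSMB10 at -0.69, and the 6 immunoproteasome and 11S genes had a median of -0.46. The 9 MHC class II genes had a median of -0.38, the 18 glycolysis genes -0.28, the 23 oxidative phosphorylation genes -0.31 and the 22 apoptosis regulators -0.25. The 41 ribosomal protein genes had a median of 0.13. For scale, the GAPDH spots of this array had a median of -0.21. The MHC class II and glycolysis medians lay inside the central 95% when random lists were matched on print position, and the MHC class II, oxidative phosphorylation and ribosomal values did so when the mean replaced the median. These 11 of 23 list medians lay outside the central 95% of random lists, against 1.15 by chance.

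Over all 14070 genes, 93 were at or above 1 and 481 at or below -1 in BTZ30. The genes furthest above 0 were CLU, the extracellular chaperone clusterin, at 3.06, LRRC37B at 2.80, LAX1 at 2.60, ERCC2, a helicase of nucleotide excision repair, at 2.50 and RUBCNL at 2.44. The genes furthest below 0 were S100A4 at -3.64, EYA2 at -3.33, FYB1 at -3.17, SLN at -3.13 and GAL, the neuropeptide galanin, at -3.11. A threshold of 1.5-fold at base 2 gave 1911 genes and 3-fold gave 167, and where genes had 2 or more agreeing probes, 12 passed. Leaving out genes beside a like feature, on the same side at 50% or more of their value, gave 216, and 321 if only genes at or beyond 0.5 were left out.

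In the BTZ100 line, selected to 100 nM, the proteasome lists lay furthest above 0. The 20S core had a median of 0.99 with all 13 genes above 0 and 6 at or above 1, namely PSMB6 at 2.33, PSMB5 at 1.52, PSMA5 at 1.24, PSMB7 at 1.18, PSMB2 at 1.11 and PSMB3 at 1.11. The 19S particle had a median of 0.91 with 14 of 16 above 0, and 7 were at or above 1, among them PSMD2 at 1.87, PSMC4 at 1.57, PSMD11 at 1.501 and PSMD14 at 1.44. The 2 19S members below 0 were PSMD6 at -0.13 and PSMD9 at -0.18. The 19 ubiquitin conjugation and removal genes had a median of 0.28, with the deubiquitinase gene USP5 at 1.41 and VCP, an ATPase that extracts ubiquitinated proteins, at 1.09. After centring on print position the median of this list was 0.17.

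**Figure D1:**
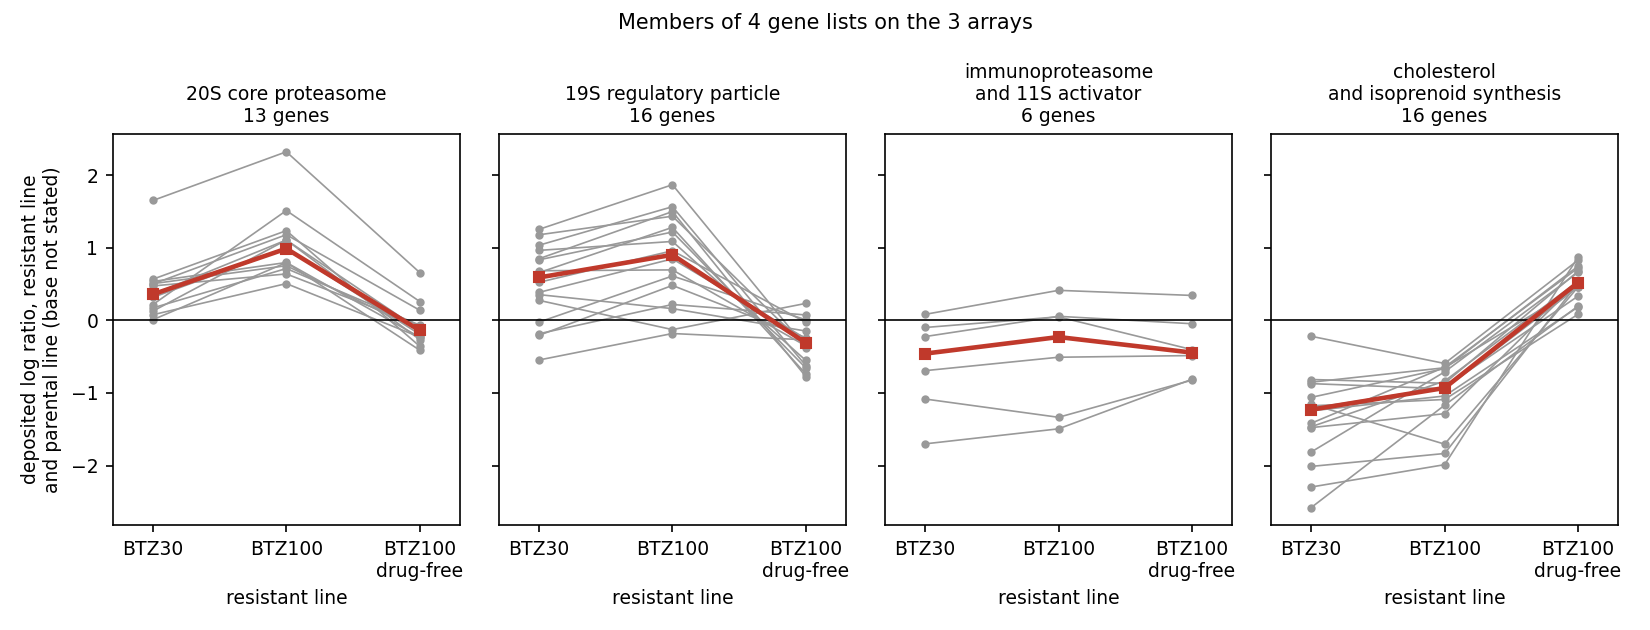
Deposited log ratio (vertical axis, base not stated) of each measured member of 4 gene lists on the 3 arrays (horizontal axis), 1 grey line per gene, with the list median in red squares and 1 array per line. The 20S core median stands at 0.36, 0.99 and -0.14, and the cholesterol and isoprenoid median at -1.23, -0.93 and 0.52, on the BTZ30, BTZ100 and drug-free arrays.

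The oxidative stress genes included members well above 0 in BTZ100. The 19 NFE2L2 and oxidative stress genes had a median of 0.24, and 4 were at or above 1. These were GCLM, a subunit of the enzyme that starts glutathione synthesis, at 2.37, SLC7A11, a cystine transporter, at 1.41, GSR, glutathione reductase, at 1.28 and PGD at 1.20. The 23 efflux and detoxification genes had a median of 0.17, with ABCA1 at 1.14 and AKR1C3 at 1.10, whereas ABCB1, the classical multidrug efflux pump, was at 0.17. The efflux list lay at percentile 97.7 of the random lists and inside their central 95% when these were matched on print position.

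Sterol synthesis genes were again all below 0 in BTZ100, with a median of -0.93 and 7 of 16 at or below -1, including DHCR7 at -1.99, MVK at -1.83, SCD, a fatty acid desaturase, at -1.71 and FDPS at -1.29. PSMB9 stood at -1.49 and PSMB8 at -1.34, while the median of their list, -0.23, lay inside the central 95%. The MHC class I median was -0.53, with HLA-E at -1.14. The myeloid median was -0.13, with FCGR1A at -2.37, ELANE, neutrophil elastase, at -1.95, PRTN3 at -1.14 and ITGB2 at -1.10. The oxidative phosphorylation median was -0.15, and its mean lay inside the central 95%. In all, 9 of 23 list medians lay outside the central 95%.

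In BTZ100, 135 genes were at or above 1 and 318 at or below -1. The genes furthest above 0 were LRRC37B at 3.41, PLEKHA7 at 3.10, TEF, a circadian transcription factor, at 2.91, CLU at 2.83 and NMB at 2.68. The genes furthest below 0 were SLN at -3.92, FADS2, a fatty acid desaturase, at -3.62, S100A4 at -3.45, PLD4 at -3.40 and CSRNP3 at -3.25. A threshold of 1.5-fold at base 2 gave 1603 genes and 3-fold gave 123, and 9 genes passed among those with 2 or more agreeing probes. The 2 settings without genes beside a like feature gave 174 and 240.

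Sterol synthesis genes lay above 0 in the drug-free line, with a median of 0.52 and all 16 above 0, DHCR7 at 0.87, SREBF1, a regulator of lipid synthesis, at 0.83, MVD at 0.75 and SQLE at 0.72. The 19S particle had a median of -0.31 with 13 of 16 below 0, among them PSMD11 at -0.77 and PSMC1 at -0.74. The 20S core had a median of -0.14, inside the central 95%, with PSMB6 at 0.66 and PSMB5 at 0.26 above 0. Ribosomal protein genes had a median of 0.46, and all 41 were above 0, on an array where the GAPDH spots had a median of 0.17.

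Inducible proteasome subunits stayed on the side below 0 in the drug-free line, PSMB8 at -0.82, PSMB9 at -0.81 and PSMB10 at -0.48, and the median of the 6 genes was -0.44. The MHC class I median was -0.21 and the myeloid median -0.12, both inside the central 95% when matched on print position, with FCGR1A at -1.45, CSF1R at -1.24 and CSF2RA at -1.03 at or below -1. The oxidative stress median was 0.14, with SLC7A11 at 1.82. No member of the 20S, 19S or sterol lists reached 1 on either side, and 7 of 23 list medians lay outside the central 95%.

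In the drug-free line 62 genes were at or above 1 and 90 at or below -1. The genes furthest above 0 were RUBCNL at 3.36, ERCC2 at 3.31, LAX1 at 2.66, NOX4 at 2.41 and MAP3K12 at 2.34. The genes furthest below 0 were FYB1 at -3.21, ST3GAL4, a sialyltransferase, at -2.29, S100A4 at -2.28, C5orf23 at -2.20 and SLN at -2.14. This array also had the narrowest spread, with a median absolute deviation of 0.168 against 0.227 and 0.193 on the BTZ30 and BTZ100 arrays. With the arrays scaled to 1 deviation the count was 276 genes, 1.5-fold, 3-fold and agreeing-probe settings gave 853, 39 and 3, and the 2 settings on adjacent features 73 and 100.

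**Figure D2:**
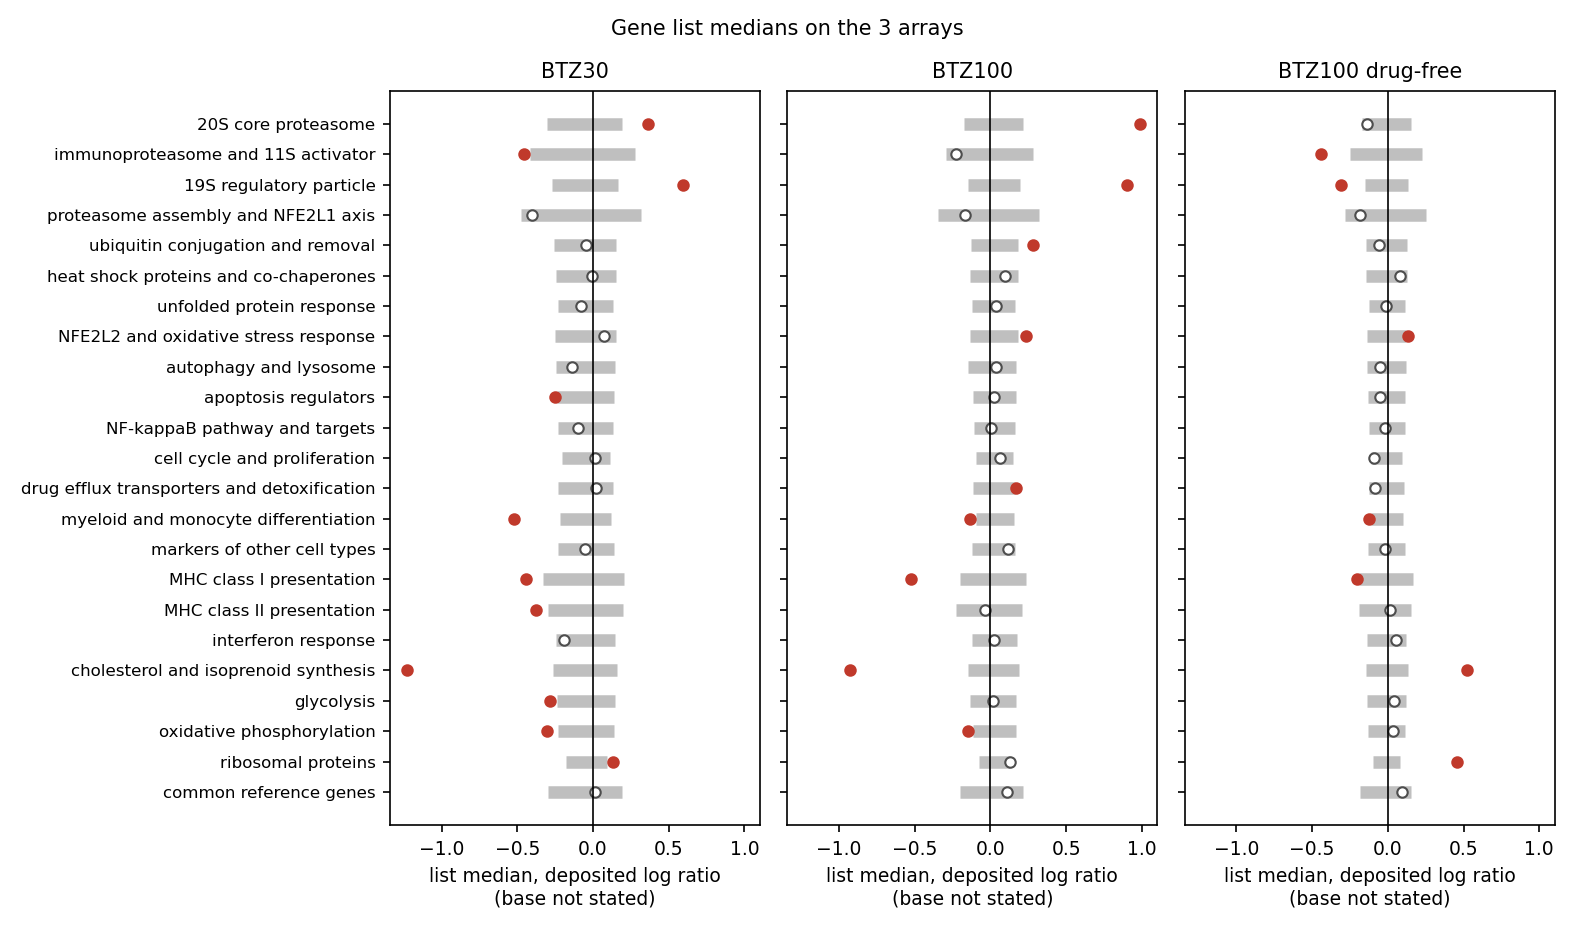
Median deposited log ratio (horizontal axis, base not stated) of 23 gene lists (vertical axis) on the 3 arrays, with the central 95% of 10000 random lists as grey bars. Red points lie outside that range, 11 on the BTZ30, 9 on the BTZ100 and 7 on the drug-free array, and open points lie inside.

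Proteasome genes stood higher on the BTZ100 array than on the BTZ30 array. The 20S core had a median difference of 0.67 with 13 of 13 above 0, the 19S particle 0.42 with 14 of 16, and PSMB5 had the largest difference of the 20S genes, 1.30. The myeloid list had a median difference of 0.30, with S100A9 at 2.60, CSF1R at 1.66, S100A8 at 1.16 and ITGAX at 1.04 above and ELANE at -1.55 below. The oxidative stress list stood at 0.28, the autophagy and lysosome list at 0.25 and the cell cycle list at 0.23, and the last 2 lay inside the central 95% when random lists were matched on print position. With the mean the oxidative stress and cell cycle lists lay inside it, and after centring on print position the cell cycle median was 0.073. The sterol list had a median difference of 0.20, inside the central 95%, with HMGCS1 at 1.41 and IDI1 at 1.10.

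At or beyond 1, 114 genes were above and 51 below in BTZ100 minus BTZ30. The largest differences above 0 after S100A9 were IL3 at 2.50, TEF at 2.48, FGF11 at 2.44, FYB1 at 2.29, KAT6B at 2.27, BARX2 at 2.26, PLEKHA7 at 2.10, SERPINF1 at 2.00, TMC6 at 1.93, UHRF1 at 1.86 and VEZF1 at 1.83. The largest below 0 were ID3 at -1.82 and ID1 at -1.66, inhibitors of helix-loop-helix transcription factors, MFF at -1.64, C5AR2 at -1.63, BEST2 at -1.61, PTP4A3 at -1.57, ELANE, KIF17 at -1.48, RFLNB at -1.46, C5orf22 at -1.44, RPUSD4 at -1.41 and CTAGE10P at -1.36. S100A9 and IL3 occupy neighbouring features, as do KAT6B and UHRF1, and values of neighbouring features correlated on these arrays. Counts were 1109 at 1.5-fold, 25 at 3-fold, 3 among genes with agreeing probes, and 47 and 88 without genes beside a like feature.

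Sterol synthesis and proteasome genes differed in opposite directions between the drug-free and BTZ100 arrays. All 16 sterol genes were at or above 1 in drug-free minus BTZ100, with a median of 1.39 and DHCR7 at 2.86, MVK at 2.35, SCD at 2.17 and FDPS at 1.81. INSIG1, at 1.17, passed only as the median of 2 disagreeing probes, at 2.48 and -0.13. Of the 29 measured 20S and 19S genes, 28 were below 0 and 18 at or below -1, with a median of -1.10. PSMD11 stood at -2.28, PSMD2 at -2.25, PSMC4 at -2.19, PSMB6 at -1.67 and PSMB5 at -1.25. PSMD6, at 0.36, was the exception.

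**Figure D3:**
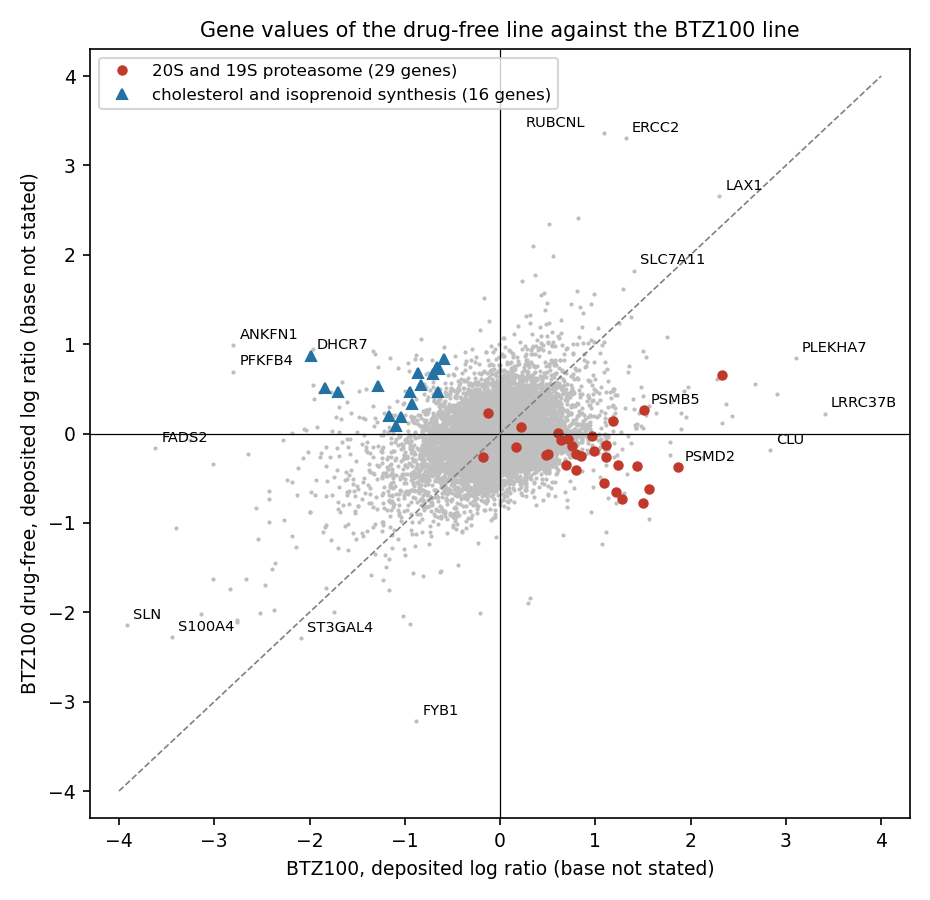
Deposited log ratio (base not stated) of each gene on the BTZ100 array (horizontal axis) and the drug-free array (vertical axis), with genes in grey, 20S and 19S proteasome genes as red circles, sterol synthesis genes as blue triangles and the line of equal values dashed. Of the 29 proteasome genes 28 lie below that line, and the 16 sterol genes lie above it.

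Other lists also differed between the drug-free and BTZ100 arrays. The ribosomal protein genes had a median difference of 0.35 with 40 of 41 above 0, and MHC class I genes 0.34, the latter inside the central 95% when the mean replaced the median. For scale, GAPDH stood at 0.15 in this difference, and random lists were not matched on intensity. The cell cycle genes stood at -0.28 with MCM5, a replication helicase subunit, at -1.34 and E2F1 at 1.46. The ubiquitin list stood at -0.28, with USP5 at -1.32 and VCP at -1.31 and a median of -0.16 after centring on print position, and the efflux and detoxification list at -0.20, with CYP1B1 at -2.15, the latter median inside the central 95% when matched on print position. The interferon response list, at 0.16, reached percentile 97.6, and lay inside the central 95% with the mean or with the arrays scaled to 1 deviation. In the oxidative stress list, whose median of -0.04 lay inside the central 95%, GCLM stood at -2.04 and GSR at -1.46.

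In drug-free minus BTZ100, 253 genes were at or above 1 and 146 at or below -1. Above 0 the largest were ANKFN1 at 3.79, PFKFB4, a regulator of glycolysis, at 3.50, FADS2 at 3.46, CSRNP3 at 3.18, VKORC1, vitamin K epoxide reductase, at 2.91, DHCR7, TBC1D30 at 2.68, BNIP3, a mitophagy receptor, at 2.51, DHX15 at 2.42, TERB1 at 2.36, MVK and PLD4 at 2.35. Below 0 the largest were LRRC37B at -3.19, CLU at -3.02, FCER2, the low-affinity IgE receptor, at -2.53, TEF at -2.46, UNKL at -2.39, FYB1 at -2.33, UHRF1 at -2.30, PSMD11, PLEKHA7 at -2.26, PSMD2, OPALIN at -2.24 and KAT6B at -2.21. Counts were 1814 at 1.5-fold, 102 at 3-fold, 7 among genes with agreeing probes, and 108 and 205 without genes beside a like feature.

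Some genes lay on the same side on all 3 arrays. At or beyond 1, 48 genes were below 0 and 7 above 0 on every array, where independent lists of these sizes would share 0.070 and 0.0039. Below 0 stood S100A4, SLN, GAL, EYA2, the beta-defensin gene DEFB103B, the glutamine transporter gene SLC38A1, ST3GAL4, GCSAML, FLRT1, ECM2, TMEM132C and MYL9. SLC38A1 had -2.26, -2.38 and -1.98 on the BTZ30, BTZ100 and drug-free arrays. Above 0 stood LAX1, SLC7A11, ERCC2, DEFB106A, RUBCNL, NAV3 and DNAJC2, followed by TM4SF18, ANKRD12, LBR, TNMD and PLEKHA7, for which at least 1 array lay under 1. A comparison added after the counts were seen used 50 simulations of unchanged lines against 1 shared parental RNA, with as many genes called per array. On average 11.4 genes were shared below 0 (5 to 18) and 2.90 above 0 (0 to 6). The simulation drew normal values of equal spread per RNA, with r of 0.50 for every pair, where the real arrays gave 0.71, 0.37 and 0.37. It modelled no dye bias, so it does not measure the sharing beyond the control. The 3 real arrays share the parental line and the dye orientation, and an unknown part of the excess may come from the shared control. Above 0 the 7 genes barely passed the simulated range, and 6 were left after centring on print position. The totals were 241 genes at 1.5-fold, 16 at 3-fold, 2 among genes with agreeing probes and 36 without genes beside a like feature.

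The genes at or beyond 1 in BTZ30 were read on the other arrays. The 93 above 0 had medians of 1.19 in BTZ30, 0.84 in BTZ100 and 0.23 in the drug-free line, and the 481 below 0 had medians of -1.35, -0.91 and -0.46. These genes were chosen on the BTZ30 array, which makes its own medians the most extreme of the 3. Across all genes Pearson's r was 0.71 between BTZ30 and BTZ100, 0.37 between BTZ30 and the drug-free line and 0.37 between BTZ100 and the drug-free line, with Spearman's rho of 0.62, 0.24 and 0.26. Simulated unchanged lines against 1 shared parental RNA gave r of 0.50. The covariances were 0.137, 0.053 and 0.050, beside 0.051 for unchanged lines if the parental RNA held an equal share of the variance of the narrowest array.

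The 71 genes named by size, counting PSMB5, rest on 1 probe each, and 94.5% of all genes had 1 probe. Where a gene had several, pairs of probes hardly correlated across genes, with r of 0.04, 0.03 and 0.04 over 870 pairs on the BTZ30, BTZ100 and drug-free arrays. The 238 pairs annotated to the same sequence record gave r of 0.0005, 0.11 and 0.06. Of these, 217 lay at 1 fixed distance in feature number, with r of 0.01, 0.11 and 0.03. They may therefore not be independent repeats of 1 sequence, which was not tested. Where 1 probe of a pair lay at or beyond 1, the other matched its side at 50% or more in 9 of 67, 4 of 70 and 0 of 27 pairs. Features with consecutive numbers correlated at 0.22, 0.28 and 0.23. LAX1, SLN, PLEKHA7, DEFB106A, GCSAML, FLRT1, ECM2, TMEM132C, CSRNP3, C5orf23, ANKFN1, VKORC1, TERB1, OPALIN, C5orf22, CTAGE10P and MFF come from the later part of each run of feature numbers, where 26.7%, 25.8% and 34.4% of spots were empty, against 5.44%, 5.02% and 6.72% in the earlier part. RUBCNL and NOX4 occupy neighbouring features, and on the BTZ100 array CLU has a neighbour on the same side at 50% or more of its own value. Such a neighbour was also found for PSMB5, LBR, GCSAML and FLRT1 on at least 1 array, and for PLEKHA7 and RFLNB in BTZ100 minus BTZ30.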

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

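The tests of print position, of culture without drug and of the neighbours of sterol probes were chosen after the results were seen, and the test of the neighbours of proteasome probes after the data were seen but before its own result.

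Gene lists with a median on opposite sides of 0 in 2 lines, each outside the central 95% of random lists, were taken for a closer look. With 1 array per line none of these differences was tested. The 19S median differed by -0.90 between the drug-free and BTZ30 arrays (-0.31 and 0.59) and by -1.21 between the drug-free and BTZ100 arrays (-0.31 and 0.91). The cholesterol and isoprenoid list differed by 1.75 between the drug-free and BTZ30 arrays (0.52 and -1.23) and by 1.45 between the drug-free and BTZ100 arrays (0.52 and -0.93). All these signs would turn if the deposited ratio were parental over resistant.

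The 29 proteasome genes had a median of -1.10 in drug-free minus BTZ100, with 28 of 29 below 0. Medians of print-position classes ran only from -0.17 to 0.13 on the BTZ100 array and from -0.049 to 0.060 on the drug-free array. A trend of that size is too small to be the whole cause. Centring each position class left a median of -0.96, but could not have removed the difference and was no separate test. A gene-specific dye bias common to both arrays cancels in the difference by design. Signal shared between adjacent features stays open, because 47 neighbours of proteasome probes, none of a proteasome gene, had a median difference of -0.39, between the bounds set for and against it. The 6 months of culture without drug also stay open as the source, since the 28 members with a lower value on the drug-free array come from 1 array per line and line and array cannot be told apart.

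The 16 sterol synthesis genes lay below 0 on the BTZ100 array and above 0 on the drug-free array. Print-position medians of the BTZ100 array, -0.17 to 0.13, were too small for a position trend to be the whole cause. Centring each class left a BTZ100 median of -0.97, but could not have removed the pattern and was no separate test. Adjacent features of no gene of the list had a BTZ100 median of -0.083 over 27 features, which argues against shared signal on that array. These neighbours were not read on the drug-free array or in the difference, so shared signal was not tested there. A difference in culture conditions such as serum or cell density at harvest was not tested, nor was the absence of drug. A response of sterol synthesis that differs with bortezomib may be put forward only as a hypothesis.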

How the results depend on the processing

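The settings on print position, adjacent features, natural logarithms and the earlier part of each run were chosen after the data were seen. Values are in the order BTZ30, BTZ100, drug-free, BTZ100 minus BTZ30, drug-free minus BTZ100 and all 3 lines together, where the counts were 574, 453, 152, 165, 399 and 55. They were 1911, 1603, 853, 1109, 1814 and 241 at 1.5-fold and 167, 123, 39, 25, 102 and 16 at 3-fold, and 1326, 1106, 515, 665, 1219 and 146 if the logarithms are natural and 2-fold is kept, which follows from the threshold. Genes with 2 or more agreeing probes gave 12, 9, 3, 3, 7 and 2, from far fewer genes. All features counted 1 by 1 gave 728, 267, 266, 639 and 106 from the second result on, from more features. Leaving out genes with a neighbour on the same side at 50% of their value or more gave 216, 174, 73, 47, 108 and 36. That setting kept 1422 of 14070 genes, since a gene near 0 has such a neighbour by chance, so a narrower form, for genes at or beyond 0.5, was added when its counts had already been seen and gave 321, 240, 100, 88 and 205 for the first 5. Scaling the arrays to 1 deviation gave 276 genes in the drug-free line. Counts with another probe summary, with another rule for missing values, after centring on print position and from the earlier part of each run stayed within 1.5 times. Spearman's rho was 0.24 and 0.26 for the 2 pairs with the drug-free line, against r of 0.37 for both.

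Of 115 list medians 42 lay outside the central 95% of random lists, and 36 to 43 did under the alternatives. The mean gave 43, with 8 of the 42 lost and 9 gained. Lost were oxidative phosphorylation in BTZ30 and BTZ100, ribosomal proteins and MHC class II in BTZ30, oxidative stress and cell cycle in BTZ100 minus BTZ30, and MHC class I and interferon in drug-free minus BTZ100. Scaling lost 3, autophagy and cell cycle in BTZ100 minus BTZ30 and interferon in drug-free minus BTZ100. The probe with the largest mean lost 3, cell cycle in BTZ100 minus BTZ30, efflux in BTZ100 and glycolysis in BTZ30, and unmatched random lists lost autophagy in BTZ100 minus BTZ30. Centring on print position lost 5 and position-matched random lists 8, among both autophagy and cell cycle in BTZ100 minus BTZ30, efflux in BTZ100 and drug-free minus BTZ100, and MHC class I in the drug-free line. No list median outside that range changed sign, while the sterol median in BTZ100 minus BTZ30, inside it, crossed 0 when scaled. Centring on print position gave 0.88, 0.56 and -1.05 for the 20S core in BTZ100 and the 2 differences, 0.80, 0.30 and -0.94 for the 19S particle, 0.084 for the sterol list in BTZ100 minus BTZ30, and 0.17 and -0.16 for the ubiquitin list in BTZ100 and drug-free minus BTZ100. The mean in place of the median gave -1.35, -1.06 and 1.58 for the sterol list in BTZ30, BTZ100 and drug-free minus BTZ100. It gave 0.47 and 0.26 for the oxidative stress list in BTZ100 and the drug-free line. For the myeloid list it gave -0.75, -0.37 and -0.24 in BTZ30, BTZ100 and the drug-free line. Scaling gave -1.06, -0.0051 and 1.496 for the sterol list in BTZ30 and the 2 differences. The cause of these shifts was not tested. No signal over background is in the deposited values, so its limit on dim genes is unknown.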

Other observations

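The tests of probe pairs, of the sign of the ratio and of neighbouring genes on chromosomes were chosen after the results were seen, whereas the gene lists and their random lists were fixed beforehand.

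The heat shock, unfolded protein response and NF-kappaB lists lay near 0 in lines selected with a proteasome inhibitor. The 18 heat shock genes had medians of -0.0062, 0.095 and 0.078 on the BTZ30, BTZ100 and drug-free arrays, with CRYAB at 1.02 in BTZ100 and HSPA4 at -1.22 in BTZ30. The 22 unfolded protein response genes had medians of -0.082, 0.036 and -0.011, with EDEM1, a factor of glycoprotein degradation in the endoplasmic reticulum, at -1.21, -1.001 and 0.48. The 25 NF-kappaB genes had medians of -0.097, 0.0010 and -0.016, with the chemokine gene CCL5 at -1.94 in BTZ30. The 5 measured proteasome assembly genes had medians of -0.41, -0.17 and -0.19, although POMP, the proteasome maturation protein, stood at 1.11, 0.98 and 0.45. All of these medians lay inside the central 95% of random lists, as did those of the 10 common reference genes, 0.014, 0.11 and 0.093, and of 21 markers of other cell types, -0.055, 0.12 and -0.017.

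Single members of lists stood apart. SQSTM1, an autophagy receptor, was at 0.26, 0.84 and -0.26 and CTSD, a lysosomal protease, at 0.74, 1.34 and -0.031 on the BTZ30, BTZ100 and drug-free arrays, in an autophagy and lysosome list with medians of -0.14, 0.037 and -0.055. BCL2, an inhibitor of apoptosis, stood at -0.82, -1.22 and -0.59 and the interferon-induced gene GBP1 at -0.89, -1.37 and -0.67. The interferon list had medians of -0.19, 0.023 and 0.051, the cell cycle list 0.012, 0.061 and -0.093.

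Pairs of named genes on consecutive features lay on the same side of 0 as each other on each array. S100A9 stood at -2.14, 0.46 and -0.09 and IL3 at -2.01, 0.49 and -0.03 on the BTZ30, BTZ100 and drug-free arrays. KAT6B stood at -1.16, 1.11 and -1.10 and UHRF1 at -0.79, 1.07 and -1.23, and RUBCNL at 2.44, 1.10 and 3.36 and NOX4 at 2.00, 0.82 and 2.41.

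Probes of 1 gene disagreed on these arrays, and no biological explanation was tested. Misplaced names in the later part of each run of feature numbers remain open. Of 238 pairs annotated to the same sequence record, 217 lay at 1 fixed distance in feature number. Whether names were shifted by that distance was not tested. The 141 pairs with both probes in the earlier part correlated at 0.082, 0.068 and 0.186 on the BTZ30, BTZ100 and drug-free arrays, against 0.026, 0.021 and 0.010 for pairs with a later probe. Little real change in genes with several probes would leave small values, apart from technical spread. The SD of the difference over 870 pairs was 0.63, 0.65 and 0.46 on the BTZ30, BTZ100 and drug-free arrays. The repeated GAPDH spots had an SD of 0.107, 0.101 and 0.080. Where 1 probe lay at or beyond 1, the other shared its side in 36 of 67, 31 of 70 and 14 of 27. A side shared about as often as not would also follow from technical spread alone, and GAPDH spots do not give the spread of other features. These values therefore cannot decide on little change as the cause for these pairs. PSMD6, the only 20S or 19S gene above 0 in drug-free minus BTZ100, was from the later part. So was the INSIG1 probe at 0.32 in BTZ100, beside the other at -2.49, and both were singled out after their values were seen. PSMD6 was with its list in BTZ30, at 0.28. In BTZ100 PSMD9, from the earlier part, lay further below 0 than PSMD6, at -0.18 against -0.13.

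The sign of the deposited ratio was examined with the proteasome genes, which are known to be induced when the proteasome is inhibited. Of 29 members 27 lay above 0 on the BTZ100 array, which is consistent with a ratio of resistant over parental, without settling it.

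A gain or loss of a chromosome segment was looked for as a run of neighbouring genes displaced together. Over medians of 40 neighbouring genes among 11239, at most 1 window of an array left the range of 50 shuffled orders. That range was -0.42 to 0.24 on the BTZ30 array, -0.26 to 0.34 on the BTZ100 array and -0.21 to 0.19 on the drug-free array. A segment that moved its genes by less, or a short one, could not be seen. The search also rests on gene names, and probes of 1 gene hardly correlated. It therefore shows only that no long run of named genes was displaced beyond that range, apart from the 1 window.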
